A study of Mus musculus with 4 samples.

How the data were processed

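Gene expression was measured by RNA sequencing in 4 mouse libraries: EtOH and 4OHT cultures of Runx1 delta/delta leukaemic cells (replicate 1) and of Runx1 delta/+ leukaemic cells (replicate 2). Per the labels' protocols, total RNA came from cells sorted by flow cytometry and libraries were made with either a TruSeq or a NEBNext RNA kit; which library had which kit is not given in the sources used here. The submitters' processing notes name the mouse build mm 9. The aligner, the counting rule, the annotation and the use of strand are not given in the sources used here.

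The deposited table has 23240 gene rows. Per the file headers, the authors gave RPKM (reads scaled by gene length and by mapped reads) for each library, with replicates kept apart. Per the file headers, the authors also deposited a fold of proportions, a p-value and a corrected p-value from Kal's Z-test of 4OHT against EtOH for each replicate number. Recomputing these from the RPKM columns showed that the test treats RPKM as counts and compares shares of summed RPKM between 2 libraries, and that the correction is Benjamini-Hochberg over all rows; such a test compares those libraries, not the conditions. No fold was given for 3544 rows in replicate 1 and 1554 in replicate 2.

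Depth was recovered from the table itself. Within a gene, RPKM values are whole multiples of the worth of 1 read, so whole read numbers, gene lengths and library totals were searched for jointly. Whole reads came out for 17213 of the 17213 genes above 0 (100%), with a tolerance of 0.02 reads, and the lengths were whole numbers at the smallest read numbers for 10491 of 10910 genes checked. The totals rested on the value shared by the most genes with a single transcript, 54 of the 301 examined. They were 34.6 and 36.7 M mapped reads for EtOH and 4OHT of replicate 1 and 33.7 and 39.4 M for replicate 2. At these depths 1 read in a gene of 1 kb is worth 0.0289, 0.0272, 0.0297 and 0.0254 RPKM, in the same order. The floor for a fold was 3 reads per library; it covers counting error only, since reads were not counted as independent molecules.

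The design had been fixed before the data were examined. It allowed for counts or normalised values; since the values are RPKM, limma was used on log2(RPKM + 1) for genes with a mean of at least 1 RPKM (9595 genes), with a trended prior, treatment and genotype as terms, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. Genotype is the same as the replicate number. It entered the model because the labels give it as a factor, so each arm holds 1 library per genotype; in the authors' deposited table, too, libraries are compared within a replicate number. Samples sharing a number deviated together from their group means (correlation across genes 0.664), and after the treatment axis (69.4% of variance) the second principal component (25.5%) separated the genotypes. The model leaves 1 residual degree of freedom, to which the prior added 4.37. Correlations of log2 values between libraries ran from 0.869 to 0.964, so none was a copy of another. Nothing says that the libraries of an arm are more than 1 culture per genotype, so p-values measure the spread left between these 4 samples.

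Gene lists (30, fixed before the data were examined, 619 entries with 591 in the table, 5 through older symbols in RefSeq) were tested with camera at a preset correlation of 0.01 for the 26 lists with at least 5 measured members, with camera at an estimated correlation and with fry beside it. The list of genes of the mitochondrial genome had 0 members in the table. With 1 residual degree of freedom the estimated correlation rests on a single residual per gene, and both it and fry had little power. For 4OHT, fry gave an adjusted p = 0.499 for erythroid genes (17 of 18 lower) and for ribosomal protein genes (0 called). Camera with the estimated correlation gave an adjusted p of 0.919 or 0.988 for every list tested. A miss in either test therefore decides neither for nor against a list. Named genes were Runx1 and Flt3, the 12 largest rises and falls with 4OHT and the 6 largest differences in each direction between genotypes (adjusted p under 0.05, mean of at least 5 RPKM, same direction in both pairs, no clone names), and up to 4 members of each list with the smallest p; not every gene so chosen is named. Further list members are named where they illustrate a count and were chosen after their values were seen. GC content and transcript lengths came from a GRCm38 annotation by symbol and covered 99.1% of tested genes; no coordinates were used.

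The fit was tested on simulated data for the comparison of 4OHT with EtOH, in 10 runs on 9595 genes with 200 changed. Of genes changed by 1 on the log2 scale 82.1% were recovered, and of those changed by 2, 99.5%. On average 6.5% of calls were false (range 1.6% to 25%), and 0 of 300 random lists were called. The simulated genes varied independently and the lists held unchanged genes only, so lists whose members move together were not tested. The simulation also changed far fewer genes than the 3113 called in the data. Alternatives were other pseudocounts and filters, a 2-fold minimum, no genotype or treatment term, each library left out, and, chosen after seeing the data, median-ratio scaling, columns set to the same sum (TPM), limma-voom on recovered reads, removal of a GC and length trend and removal of the erythroid list. The planned count-model alternatives were left out; limma-voom was the only fit to recovered reads. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.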

Results

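RNA was sequenced from leukaemic bone marrow cells of mice, sorted as positive for GFP and BFP and negative for the myeloid surface markers CD11b and Gr1. The labels call these cells a RUNX1 and FLT3-ITD acute myeloid leukaemia; FLT3-ITD is an activating internal tandem duplication of the FLT3 receptor. Cells had been cultured for 22 h with the cytokines FLT3L, SCF, IL3 and IL11 and with either 200 nM 4OHT or the same volume of its solvent, ethanol (EtOH). 4OHT is 4-hydroxytamoxifen, the active form of tamoxifen, which is widely used to switch proteins fused to a modified oestrogen receptor domain; the labels do not say which protein it acts on here. There were 4 libraries: EtOH and 4OHT for replicate 1, from Runx1 delta/delta cells, and EtOH and 4OHT for replicate 2, from Runx1 delta/+ cells. Each arm therefore held 1 library per genotype, and nothing in the labels says whether the 2 libraries of a genotype came from 1 mouse. Depth recovered from the RPKM steps was 34.6 and 36.7 M mapped reads for EtOH and 4OHT in Runx1 delta/delta, and 33.7 and 39.4 M in Runx1 delta/+. Globin genes held 12.3% of the summed RPKM of EtOH replicate 1 and 7.65% of EtOH replicate 2, against 0.917% and 0.657% of the 4OHT libraries.

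Runx1, the transcription factor whose alleles define the genotypes, was measured first. It stood at 568 RPKM in EtOH and 380 RPKM in 4OHT in Runx1 delta/delta, and at 555 and 328 RPKM in Runx1 delta/+. It fell by 0.67 on the log2 scale with 4OHT (SE 0.12, lower in both pairs, limma adjusted p = 0.0129), and this call was lost without the genotype term (adjusted p = 0.119) and with no filter on low values (adjusted p = 0.0506). Runx1 did not differ detectably between the genotypes (log2 change 0.12, SE 0.12, limma adjusted p = 0.491). The table gives 1 value per gene, which could include reads from exons outside a deleted part or from a vector-borne copy, so the labels were not checked against it. Flt3, the receptor gene named in the titles, had 12.6 and 16.8 RPKM in EtOH and 4OHT of Runx1 delta/delta and 46.3 and 39.7 RPKM in Runx1 delta/+, with no call for 4OHT (log2 change 0.08, SE 0.19, limma adjusted p = 0.752).

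**Figure D1:**
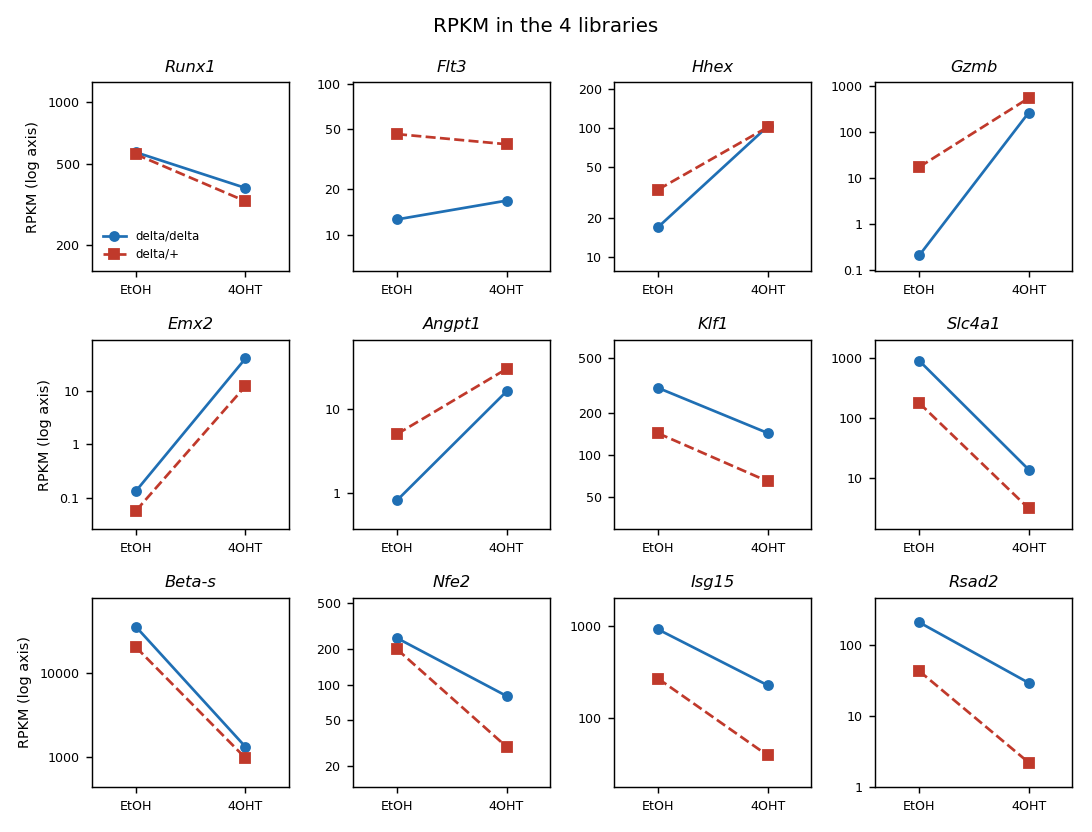
RPKM on a log axis in EtOH and 4OHT for 12 named genes, with a line joining the 2 libraries of each genotype and 1 library per point. Runx1 runs from 568 to 380 and from 555 to 328, while Gzmb reaches 259 and 536 RPKM with 4OHT.

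The comparison of 4OHT with EtOH asks which transcripts changed within 22 h of 4OHT. The largest rises were those of Gzmb and Emx2, and 17 of 18 measured erythroid genes fell. The largest rise was that of Gzmb, the cytotoxic protease granzyme B, from 0.204 to 259 RPKM in Runx1 delta/delta and from 17.0 to 536 RPKM in Runx1 delta/+ (log2 change 6.32, SE 0.63, limma adjusted p = 0.00425). Emx2, a homeobox transcription factor, went from 0.134 to 40.2 and from 0.0571 to 12.2 RPKM (log2 change 4.42, SE 0.36, limma adjusted p = 0.00315). Metrnl, a secreted protein of the meteorin family, rose 73.8-fold and 35.6-fold in the 2 genotypes, and Abca2, a lipid transporter, 16.9-fold and 11.8-fold. Dpp4, the surface peptidase CD26, rose 45.8-fold and 16.4-fold, and Tmem173, the cytosolic DNA sensing adaptor STING, 88.0-fold and 41.0-fold. Cd244, a receptor of natural killer and other cytotoxic cells, reached 11.4 and 9.03 RPKM from below 0.3 RPKM, and Prss34, a mast cell and basophil protease, reached 79.6 and 11.3 RPKM from 3.04 and 1.81 RPKM. Tuba8, Cmtm7, Scin and Slc22a3 completed the 12 largest rises, with log2 changes of 3.64, 3.52, 3.45 and 3.30. Scin, which encodes the actin-severing protein scinderin, went from 2 reads to 1079 in Runx1 delta/delta. Without the genotype term 8 of these 12 rises still passed; Gzmb, Tuba8, Cmtm7 and Prss34 did not. Gzmb has close relatives in the granzyme family, so reads could be split between copies.

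The 12 largest falls were led by Pyy, which encodes the gut hormone peptide YY, from 256 to 0.109 RPKM in Runx1 delta/delta and from 45.1 RPKM to 0 in Runx1 delta/+, the latter at least 295-fold lower against a floor of 3 reads. Add2, a protein of the red cell membrane skeleton, fell 80.2-fold and 164-fold (log2 change -5.79, SE 0.18, limma adjusted p = 5.78e-04). Slc4a1, the red cell anion exchanger band 3, fell 65.5-fold from 918 RPKM and 57.4-fold from 181 RPKM (log2 change -5.70, SE 0.17, limma adjusted p = 5.78e-04). Cldn13, an erythroid claudin of mice, fell 30.4-fold and 141-fold, and Aqp1, a water channel of red cells, stood at 89.0 and 25.2 RPKM in EtOH and at 1.86 and 0.0552 RPKM in 4OHT. Beta-s, a beta globin gene, was the most abundant of them and went from 35081 to 1312 and from 20048 to 965 RPKM (log2 change -4.56, SE 0.11, limma adjusted p = 5.78e-04); globin genes are near copies of each other, so the value of each is uncertain. Cd24a, a surface glycoprotein of developing blood cells, fell 20.9-fold and 36.1-fold. Tnfrsf13c, Hpn, Col5a1 and Tspan32 had log2 changes of -4.99, -4.49, -4.23 and -4.20. Of the 12 falls, 11 also passed without the genotype term and Slc4a1 did not.

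Across 9595 genes with a mean of at least 1 RPKM, 3113 passed the threshold in limma (Benjamini-Hochberg adjusted p under 0.05), 2130 higher and 983 lower with 4OHT, and 1210 of them changed at least 2-fold (709 higher, 501 lower). The median log2 change of all 9595 genes was 0.16, so the split between rises and falls depends on the scaling: with median-ratio scaling, where that median is -0.02, 2546 genes passed, 1221 higher and 1325 lower. With the GC and length trend removed the split was 1498 higher and 1309 lower. Fitted without the genotype term (no replicate block), 233 genes passed, all of them among the 3113, and 3 passed when EtOH replicate 1 was also left out. The model with genotype leaves 1 residual degree of freedom per gene, so the p-values rest on the spread pooled over genes. The library kit of each sample is not given, so a kit difference between EtOH and 4OHT libraries cannot be excluded.

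Red cell genes fell as a group. Of 18 measured erythroid genes, 17 fell and 0 rose (18 fell when adjusted over the list alone), with a median log2 change of -2.72 against 0.16 for all genes (camera adjusted p = 4.58e-17 with a preset correlation, adjusted p = 0.919 with an estimated correlation). The haem synthesis enzyme gene Alas2 fell by 3.37 on the log2 scale and the transferrin receptor gene Trfr2 by 3.49. The erythroid master regulators fell less: Klf1 went from 305 to 145 and from 144 to 65.3 RPKM (limma adjusted p = 0.00532), and Gata1 fell by 0.69 on the log2 scale (limma adjusted p = 0.0212). Hba-a1 did not pass (log2 change -0.86, limma adjusted p = 0.0564). Megakaryocyte and platelet genes went down in the same libraries, 9 of 13 measured members falling and 2 rising (10 and 3 when adjusted over the list alone), with a median of -1.92 (camera adjusted p = 5.5e-05, adjusted p = 0.919 with an estimated correlation). Platelet factor 4 (Pf4) fell 7.48-fold and 3.99-fold, the platelet glycoprotein gene Gp5 4.18-fold and 7.11-fold, and the transcription factor gene Nfe2 3.12-fold and 6.80-fold, while Itgb3 and Fli1 rose by 1.36 and 1.15 on the log2 scale. Without the genotype term 7 of the 17 erythroid falls and 4 of the 11 megakaryocyte calls still passed.

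Interferon response genes fell in both genotypes. Of 23 measured, 18 fell and 0 rose (21 fell when adjusted over the list alone), with a median log2 change of -1.20 (camera adjusted p = 3.72e-14, adjusted p = 0.919 with an estimated correlation). Isg15, a ubiquitin-like interferon product, went from 919 to 227 RPKM in Runx1 delta/delta and from 268 to 39.0 RPKM in Runx1 delta/+ (log2 change -2.38, SE 0.20, limma adjusted p = 0.00315). Rsad2, which encodes the antiviral enzyme viperin, fell 7.11-fold and 19.4-fold, Ifit1 10.3-fold and 61.3-fold, and the regulator Irf7 2.82-fold and 5.23-fold. Mx1 and Bst2 did not pass (log2 changes 0.10 and -0.26). The list medians were -1.28 in Runx1 delta/delta and -1.46 in Runx1 delta/+. These genes also differed between genotypes, and without the genotype term 1 of the 18 calls passed.

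Ribosome biogenesis genes rose together while genes of the ribosome itself did not pass the test. All 28 measured biogenesis genes rose (28 when adjusted over the list alone), with a median log2 change of 0.92 (camera adjusted p = 2.59e-08, adjusted p = 0.919 with an estimated correlation); 21 rose with median-ratio scaling, and 1 rose without the genotype term. Gnl3, the nucleolar protein nucleostemin, rose from 13.8 to 37.1 and from 35.3 to 90.6 RPKM (log2 change 1.35, SE 0.13, limma adjusted p = 0.00416), and Rrp9 and the RNA polymerase I subunit gene Polr1b rose by 1.47 and 1.20 on the log2 scale. Of 24 ribosomal protein genes 0 passed in limma, and their median of 0.06 became -0.15 with median-ratio scaling. Cell cycle genes lay slightly lower, more so in Runx1 delta/delta. The G2 and mitosis median was -0.59 in Runx1 delta/delta and -0.15 in Runx1 delta/+, and the S phase median -0.42 and -0.14. Of 24 G2 and mitosis genes 5 fell and 0 rose (3 fell when adjusted over the list alone; median -0.34, camera adjusted p = 3.11e-06), among them Mki67 from 252 to 98.2 and from 253 to 158 RPKM. Of 24 S phase genes 5 fell and 0 rose (5 fell when adjusted over the list alone; median -0.31, camera adjusted p = 1.54e-04), among them the cyclin E1 gene Ccne1, which fell by 1.09 on the log2 scale, and Pcna, which fell by 0.57. Both lists had an adjusted p = 0.919 with an estimated correlation. With median-ratio scaling 9 G2 and mitosis genes and 8 S phase genes fell, and with the GC and length trend removed 11 and 8 did. The S phase call was lost without 4OHT replicate 2 (adjusted p = 0.0748) and without EtOH replicate 1 (adjusted p = 0.39), each fitted without the genotype term.

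Integrated stress response genes were mixed, 8 of 18 falling and 3 rising (9 and 3 when adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.00307, adjusted p = 0.919 with an estimated correlation; adjusted p = 0.115 without 4OHT replicate 2 and the genotype term). The stress transcription factor gene Ddit3 fell from 41.0 to 13.7 and from 51.7 to 17.3 RPKM and Gadd45a fell by 2.50 on the log2 scale, while the amino acid transporter genes Slc7a5 and Slc3a2 rose by 1.08 and 0.73 on the log2 scale. Of 14 measured genes described as RUNX1 targets, 4 rose and 5 fell (4 and 7 when adjusted over the list alone). The list median was -0.75 and the mean 0.11, since Gzmb alone rose by 6.32. Its camera call (direction down, adjusted p = 0.0466) was lost with median-ratio scaling (adjusted p = 0.241), with the GC and length trend removed (adjusted p = 0.137), without the genotype term (adjusted p = 0.114) and with an estimated correlation (adjusted p = 0.919). Among these genes the homeobox gene Hhex rose from 17.0 to 102 and from 33.1 to 101 RPKM (log2 change 2.05, SE 0.24, limma adjusted p = 0.00591), the myeloid regulator Cebpa rose by 1.96 and the IL3 receptor gene Il3ra by 1.24, while Gfi1b fell by 0.86.

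The other lists did not pass camera. Cholesterol synthesis genes came nearest, 7 of 23 rising and 0 falling (camera adjusted p = 0.0584), with Dhcr7 up by 1.33 and Lss by 1.09 on the log2 scale; 2 rose and 1 fell with median-ratio scaling. Of 13 stem and progenitor genes 6 rose and 3 fell: the Tie2 ligand gene Angpt1 rose by 2.80 on the log2 scale, Myb rose by 1.82 and Ikzf2 by 1.35, while Lmo2 fell 6.89-fold and 7.81-fold. STAT5 and cytokine response genes had 7 rises and 2 falls among 18, with Il2ra up by 2.18 and Etv5 by 1.91, and Pim1 down from 148 to 51.8 and from 148 to 45.6 RPKM. Inflammatory cytokine and NF-kB genes had 6 rises, among them Il6 (1.81) and Tnf (1.71), and 5 falls, among them Relb (-2.25) and Nfkbia (-1.91), of 15 measured. Immediate early genes split 4 up and 3 down of 13, with Egr1 up and Dusp1 down (log2 change -2.12). Mast cell, basophil and eosinophil genes had 3 rises and 0 falls among 10: Prss34, the carboxypeptidase gene Cpa3 (0.637 to 24.2 and 1.84 to 8.66 RPKM) and the IgE receptor gene Ms4a2 (0.859 to 14.2 and 1.09 to 4.60 RPKM). The p53 targets had 5 rises and 4 falls among 25, RUNX and core-binding-factor genes 3 and 2 among 8 (Cbfb up by 1.21), adhesion and homing genes 4 and 5 among 16, MYC-linked metabolic genes 4 and 2 among 20, and apoptosis regulators 3 and 2 among 17. With median-ratio scaling these 5 lists had 3 rises and 6 falls, 0 and 2, 1 and 5, 2 and 4, and 2 and 3, in the same order, and Cbfb no longer passed. Primary granule genes had 2 rises and 0 falls among 5, later granule and neutrophil genes 1 and 2 among 8, monocyte and macrophage genes 0 and 2 among 5, dendritic cell and MHC class II genes 1 and 1 among 5, oestrogen receptor response genes 1 and 1 among 7, and replication-dependent histone genes 0 and 2 among 9. The T and NK cell list and the stromal and endothelial list had 1 measured gene each, Lck without a call and Pecam1 with a rise of 0.53, and the B cell list had 0. Adjusted over the list alone, counts differed for cholesterol synthesis (6 up, 0 down), STAT5 (8, 2), inflammatory (6, 7), immediate early (4, 7), mast cell (3, 2), p53 (5, 6), MYC-linked (5, 3), stem and progenitor (6, 4) and RUNX and core-binding-factor genes (4, 2). The median and mean differed in sign for adhesion genes (0.15 and -0.18), dendritic cell genes (0.08 and -0.05), monocyte genes (0.23 and -0.44), inflammatory genes (-0.42 and 0.12) and mast cell genes (-0.26 and 0.61). Camera, which compares a list with all other genes, pointed down, without a call, for these 5 lists. It also did so for the apoptosis, MYC-linked, oestrogen receptor, ribosomal protein and stem and progenitor lists, whose medians and means were positive. The stem and progenitor, MYC-linked and oestrogen receptor medians (0.435, 0.205 and 0.174) lay above the 0.163 of all genes. For the lists with these medians camera's direction is therefore no sign of a smaller median rise. The apoptosis and ribosomal protein medians (0.029 and 0.059) lay below 0.163.

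The direction of change was mostly the same in the 2 genotypes. The log2 ratios of 4OHT to EtOH had the same sign in Runx1 delta/delta and Runx1 delta/+ for 7801 of 9595 genes (81.3%), and their correlation across genes was 0.849 (Pearson) and 0.808 (Spearman); genes are not independent replicates. No gene moved by more than 1 on the log2 scale in opposite directions (0 genes). The size of the change differed for some lists, in either direction. The stem and progenitor median was 0.76 in Runx1 delta/delta and 0.11 in Runx1 delta/+, and the integrated stress response median -0.20 and -0.64. The difference between the genotypes' responses could not be tested, since it leaves 0 degrees of freedom. In the authors' deposited table, which compares 1 library with 1 library by Kal's Z-test within each replicate number, 631 genes were higher and 293 lower in replicate 1 at an FDR under 0.05, and 221 higher and 223 lower in replicate 2. In the authors' deposited table, genes higher in both replicates numbered 193 and those lower in both 156, while 3 were higher in replicate 1 and lower in replicate 2; 181 of those higher in both and 155 of those lower in both also passed limma in the same direction.

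**Figure D2:**
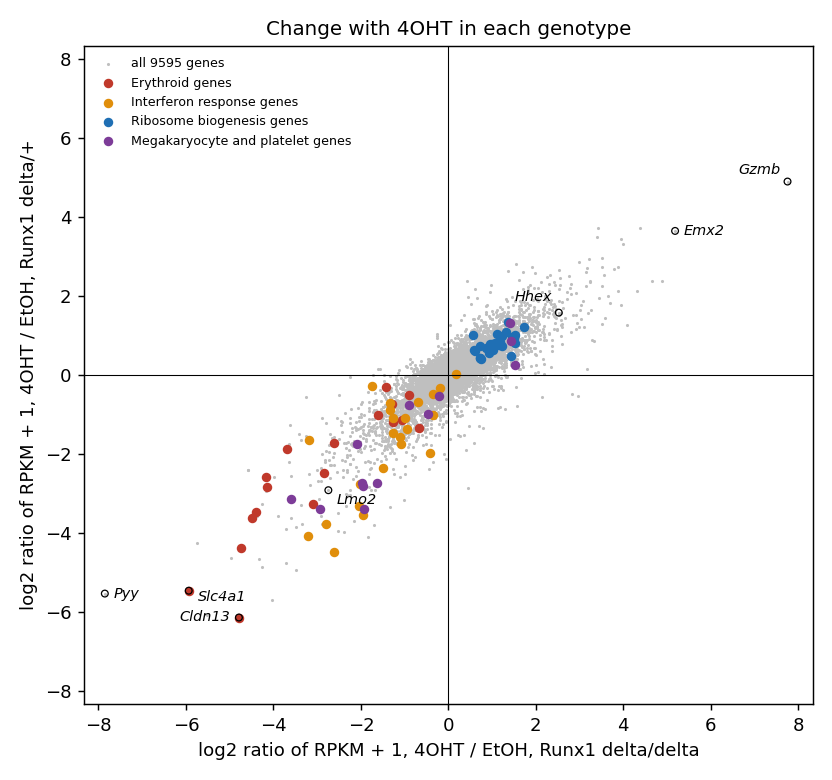
Log2 ratio of RPKM + 1 for 4OHT over EtOH in Runx1 delta/delta (horizontal) and Runx1 delta/+ (vertical) for 9595 genes, each ratio from 1 library per arm, with 4 gene lists in colour. Erythroid genes lie at the lower left and all 28 ribosome biogenesis genes at the upper right.

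The comparison of Runx1 delta/delta with Runx1 delta/+ asks what differs with the number of deleted Runx1 alleles. Of 23 measured interferon response genes 18 were higher in Runx1 delta/delta, and 7 of 20 MYC-linked metabolic genes were lower. Ifi27l2a, an interferon-induced gene, was 11.8-fold higher in EtOH and 18.1-fold higher in 4OHT (log2 change 3.66, SE 0.17, limma adjusted p = 0.00677). The 2',5'-oligoadenylate synthetase genes Oas2 and Oas1g were 6.80-fold and 10.9-fold higher in EtOH, and Rtp4 and Rsad2 4.24-fold and 4.84-fold. Apol9b, from a family of close copies, was also among the 6 largest (log2 change 2.90). Lower in Runx1 delta/delta were Ankrd37, a hypoxia-induced gene, 7.16-fold in EtOH and 5.84-fold in 4OHT (log2 change -2.23, SE 0.19, limma adjusted p = 0.0126), Ddx26b (5.19-fold and 4.47-fold), the pyruvate kinase gene Pkm2 (4.14-fold and 3.88-fold) and the brain-type aldolase gene Aldoc (4.36-fold and 3.94-fold). Ppia and Atp6v0c-ps2 (log2 changes -2.04 and -2.12) share sequence with pseudogenes or a parent gene and are uncertain. Flt3 was 3.66-fold and 2.36-fold lower in Runx1 delta/delta (log2 change -1.49, SE 0.19, limma adjusted p = 0.0204).

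In limma 1112 genes passed for genotype, 449 higher and 663 lower in Runx1 delta/delta, 390 of them at least 2-fold. Scaling moved that split: 267 higher and 1322 lower with columns set to the same sum, 299 and 256 with the GC and length trend removed, 327 and 887 with limma-voom on recovered reads. 0 genes passed in limma without the treatment term (880 at an unadjusted p under 0.05) or with no filter on low values (3906 at an unadjusted p under 0.05). The 2 libraries of a genotype may come from 1 leukaemia, and the library kit of each sample is not given, so genotype, leukaemia and batch cannot be told apart.

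Of 23 interferon response genes 18 were higher and 0 lower in Runx1 delta/delta (19 higher when adjusted over the list alone; median log2 change 1.82, camera adjusted p = 5.98e-14, adjusted p = 0.886 with an estimated correlation). Isg15 was 3.43-fold higher in EtOH and 5.81-fold in 4OHT, and Irf7 4.87-fold and 9.05-fold. Erythroid genes were higher for 6 of 18 and lower for 1 (7 and 1 when adjusted over the list alone; median 0.53, camera adjusted p = 1.53e-04, adjusted p = 0.886 with an estimated correlation), with Slc4a1 5.07-fold and 4.44-fold higher and Hbb-b2 lower. Later granule and neutrophil genes were higher for 4 of 8 (5 when adjusted over the list alone; camera adjusted p = 0.00291, adjusted p = 0.886 with an estimated correlation), among them the calprotectin gene S100a8, 3.22-fold and 3.16-fold. Immediate early genes were higher for 4 of 13 (5 when adjusted over the list alone; camera adjusted p = 0.00498, adjusted p = 0.886 with an estimated correlation), namely Jun, Junb, Jund and Ier2 with log2 changes of 1.42, 1.58, 1.53 and 1.05. S phase genes were higher for 3 of 24 (8 when adjusted over the list alone; camera adjusted p = 5.55e-06, adjusted p = 0.886 with an estimated correlation). Lower were 7 of 20 MYC-linked metabolic genes (10 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.00498, adjusted p = 0.886 with an estimated correlation), all 7 of them glycolytic or glucose transport genes such as Eno1 (3.05-fold and 3.28-fold) and Slc2a1 (3.27-fold and 3.18-fold), 5 of 28 ribosome biogenesis genes (5 when adjusted over the list alone; camera adjusted p = 0.00412, adjusted p = 0.936 with an estimated correlation), and 4 of 23 cholesterol synthesis genes, with 1 higher (7 and 1 when adjusted over the list alone; camera adjusted p = 0.00605, adjusted p = 0.886 with an estimated correlation). Other scalings moved these counts: 1 S phase gene was higher with columns set to the same sum, with limma-voom or with the GC and length trend removed. Ribosome biogenesis genes lower numbered 7 with the same sum and 2 with the trend removed, and cholesterol synthesis genes lower 7 and 2. The other 18 tested lists did not pass camera between genotypes, and these included the RUNX1 targets, with 1 gene higher and 1 lower of 14, a median of 0.17 and a mean of -0.01. The STAT5 and oestrogen receptor lists also had a positive median and a negative mean, and camera pointed up for the adhesion, G2 and mitosis and p53 lists although both were negative.

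**Figure D3:**
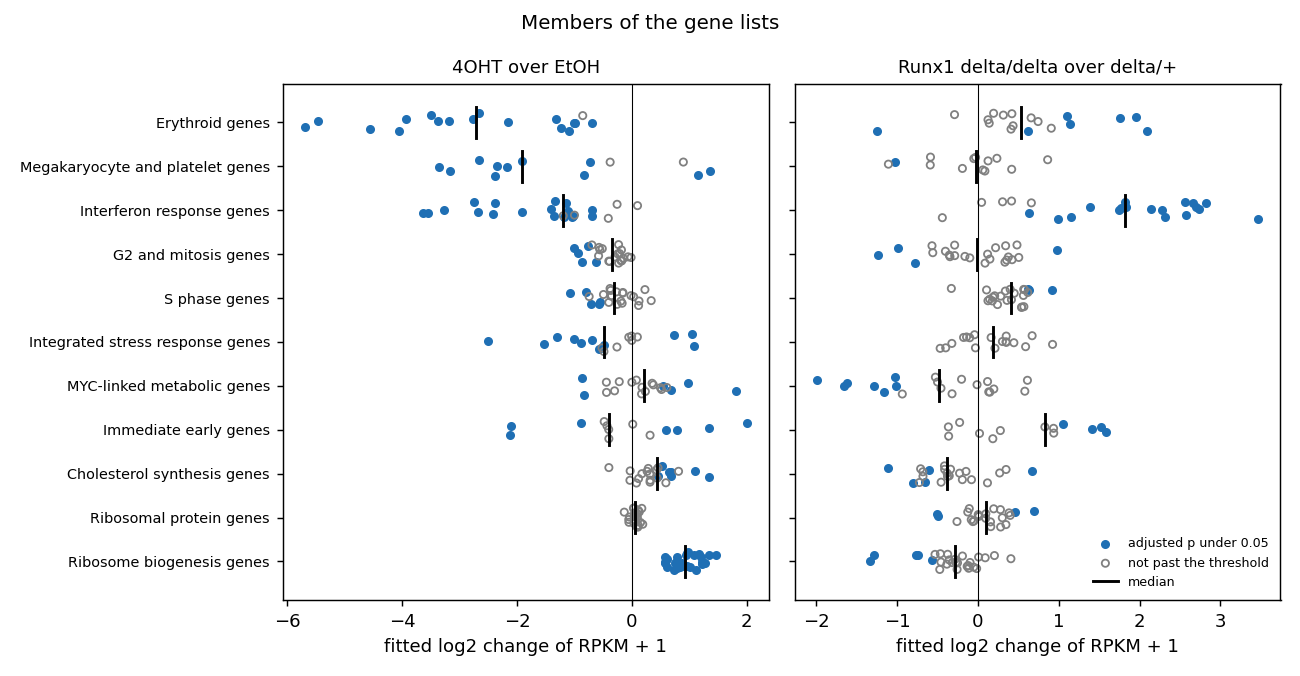
Fitted log2 change of RPKM + 1 for each measured member of 11 gene lists, for 4OHT over EtOH (left) and Runx1 delta/delta over delta/+ (right); filled points had a limma adjusted p under 0.05 and bars are medians. Interferon response genes have a median of -1.20 on the left and 1.82 on the right.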

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

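The tests in this part were all chosen after the result was seen.

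Some responses to 4OHT ran in opposite directions in the 2 genotypes by more than 0.3 on the log2 scale each; with 1 library per arm and genotype the difference was not tested. The median of the adhesion and homing genes was 0.51 in Runx1 delta/delta and -0.36 in Runx1 delta/+, a difference of 0.87. The median of the mast cell, basophil and eosinophil genes was 0.50 and -0.76, a difference of 1.26. Ctsg had log2 ratios of 0.37 and -0.63, a difference of 1, and Birc2 of -0.33 and 0.38, a difference of -0.71.

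The erythroid losses and the many rises with 4OHT moved together, in libraries whose globin share fell from 12.3% and 7.65% to 0.917% and 0.657%. Loss of other cells that had made less than 50% of the RNA of the EtOH libraries cannot raise any transcript more than 2-fold. Yet 707 genes past the threshold rose by more than that in both genotypes. This does not cover a larger loss or a gain of other cells, which were not tested and stay open for the rises. Freed reads alone do not account for all rises, since the globin share allows a rise of all other genes of at most 1.14-fold. With the erythroid list left out and the columns rescaled, 1649 genes were still higher, against 2513 with the rescaling alone. Part of the smaller rises may therefore rest on freed reads. For the erythroid falls themselves, a change in which cells passed the sort and a change of programme within the same cells cannot be told apart: the list spans 5.001 on the log2 scale from Slc4a1 to Gata1, and bulk values allow any mixture of both. An action of 4OHT on the cells' own programme may account for the rises, as a hypothesis.

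Among genes known from cytotoxic cells, Gzmb and Cd244 rose with 4OHT in both genotypes, with no test of these genes as a group: Gzmb to 259 and 536 RPKM and Cd244 to 11.4 and 9.03 RPKM. T or NK cells among the sorted cells would bring their other abundant transcripts. Of 15 further genes on the T and NK cell list, the highest in a 4OHT library was Cd247 at 0.881 RPKM, 0.34% of Gzmb, and Cd3e was at 0 in all 4 libraries. Prf1, which encodes perforin, stayed low, at 0 and 0.297 RPKM with 4OHT. Expression of Gzmb and Cd244 by the leukaemic cells themselves remains a hypothesis, and reads shared among granzyme copies were not tested.

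The 4OHT library of replicate 1 had reads for many genes that are silent in blood. Reads were found for 291 of 1123 olfactory receptor genes, against 70, 16 and 20 in EtOH replicate 1, EtOH replicate 2 and 4OHT replicate 2, and 2007 genes had reads in this library alone, at a median of 0.01995 RPKM. Depth is not the reason, since the deepest library, 4OHT replicate 2, detected 20 of these receptor genes. A trace of genomic DNA is a candidate source: at the read density of the vomeronasal receptor genes, 308 olfactory receptor genes would be expected, close to the 291 seen. None of the 2007 genes reached 1 RPKM (0 genes), so they did not enter the main tests. They did enter the fits with no filter on low values. Other evenly spread reads stay open, and no biological explanation was tested.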

How the results depend on the processing

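Scaling, voom, GC and length, and the erythroid list were alternatives chosen after the results were seen, as were the left-out libraries for genotype and lists. The planned count-model alternatives were not run. For 4OHT, 1210 genes passed with a 2-fold minimum and 233 with no replicate block; leaving out 1 library each, without the block, gave 3 (without EtOH replicate 1) to 245, and 206 and 234 for the others. The other settings gave 2209 to 3394. Runx1 kept its fall of -0.67 but missed the threshold with no filter on low values and with no replicate block, and missed it in all 4 fits with a library and the block left out (adjusted p 0.247 to 0.454 in limma), at -0.65 and -0.78 (EtOH and 4OHT replicate 1) and -0.69 and -0.56 (replicate 2). For genotype, 390 genes passed with a 2-fold minimum, 646 at a mean of at least 5 RPKM, 555 with the GC and length trend removed, and 0 with no filter; without the treatment term 0 passed with all 4 libraries (880 at an unadjusted p under 0.05 in limma) and 0 when a library was left out as well (169 to 627), so the 0 came with the dropped term already. Of 8 lists called for 4OHT and 8 for genotype, 0 and 0 passed with an estimated correlation and 0 and 0 with fry. With 1 residual degree of freedom these tests had little power, so their misses do not decide against a list. Leaving out 1 library and the block moved the number of lists called for 4OHT both up and down. The share of genes with the same direction in both genotypes was 81.3%, and 81.7% at a mean of at least 5 RPKM; another pseudocount cannot change it. With a library and the block left out, 3084, 3104, 3105 and 3089 of the 3113 genes called for 4OHT kept their sign (without EtOH and 4OHT replicate 1, then EtOH and 4OHT replicate 2), and all 3113 did with the block alone left out. With a library and the treatment term left out, 1074 to 1106 of the 1112 genes called for genotype did, and 1096 of 1097 tested did with the GC and length trend removed. Named genes that reversed were Pecam1 at -0.24 without EtOH replicate 1 and -0.23 without 4OHT replicate 2, and Pkm2 at 0.10 without 4OHT replicate 1 and 0.15 without EtOH replicate 2; the lone library of an arm was assumed to vary like the others. The cause of these changes was not tested. With the block left out, 70 results of named genes for 4OHT missed the threshold that they had passed. The 53 that did not change include genes, such as Flt3, that had not passed with the block either. With a library left out as well, more results missed the threshold than did not change. Depth limits genes under 3 reads, for which folds are bounds.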

Other observations

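Of the tests here, that of the hypoxia targets was set before their values were seen and the others after; the genes named were chosen after their values were seen.

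Some cytokine receptor genes changed with 4OHT, with no test of such genes as a group. Il3ra, the IL3 receptor alpha chain, rose from 3.24 to 10.3 RPKM in Runx1 delta/delta and from 3.38 to 8.17 in Runx1 delta/+, while the shared beta chain gene Csf2rb fell from 236 to 112 and from 235 to 169 RPKM, and its mouse-specific IL3 partner Csf2rb2 from 192 to 37.2 and from 184 to 50.8 RPKM. The 2 beta chain genes are close copies and their values are uncertain. Epor, the erythropoietin receptor gene, fell by 1.01 on the log2 scale (limma adjusted p = 0.0142). Kit, the SCF receptor gene, stayed under 1 RPKM on average but had 14 and 306 reads in EtOH and 4OHT of Runx1 delta/delta and 17 and 151 in Runx1 delta/+.

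Esr1, the oestrogen receptor alpha gene, was among the abundant transcripts, at 194 and 119 RPKM in EtOH and 4OHT of Runx1 delta/delta and at 274 and 192 RPKM in Runx1 delta/+. It fell with 4OHT (log2 change -0.61, SE 0.13, limma adjusted p = 0.0199) by about as much as Runx1 (-0.67). A fusion of RUNX1 to an oestrogen receptor domain, carried by a vector, is a candidate source of both, as a hypothesis. A single transcript as the only source would keep the ratio of Esr1 to Runx1 fixed, but that ratio was 0.341, 0.312, 0.493 and 0.585 in EtOH and 4OHT of replicates 1 and 2, a 1.87-fold range. A fusion transcript beside the cell's own Runx1 transcripts stays open, since reads per exon were not analysed here.

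Every library had reads assigned both to Xist, the RNA made from the inactive X chromosome, and to genes of the Y chromosome. Xist was at 27.1, 14.9, 78.7 and 58.1 RPKM and Eif2s3y at 6.94, 5.42, 17.7 and 15.05 RPKM in EtOH and 4OHT of replicates 1 and 2. Kdm5d, Ddx3y, Eif2s3y and Uty each had at least 123 reads assigned to them in every library. Xist (-1.70), Eif2s3y (-1.28) and Ddx3y (-1.38) were all lower in Runx1 delta/delta on the log2 scale (limma adjusted p = 0.0126, 0.0168 and 0.0254), whereas another share of male and female cells alone would move Xist and the Y genes in opposite directions. Whether cells of both sexes are the source is left open. Reads of X copies assigned to Y copies stay open: Eif2s3y exceeded its X copy in all 4 libraries, but it was the only 1 of 4 Y genes to do so, and Ddx3y was at 2.30%, 1.82%, 3.99% and 4.44% of Ddx3x.

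The 7 MYC-linked metabolic genes lower in Runx1 delta/delta act in glycolysis or glucose transport, a grouping made after their values were seen and not tested as a list, and are also targets of the hypoxia-inducible factors. If that programme differed, its targets outside glycolysis should be lower too. Of 16 such genes measured, 15 had lower values and 5 passed in limma, with 0 higher, at a median log2 change of -0.61, and Bnip3 (-1.89), Pdk1 (-1.87) and Vegfa (-1.05) were among those 5. A weaker hypoxia-inducible factor programme in the Runx1 delta/delta libraries may therefore accompany the glycolytic difference, as a hypothesis. Reads shared with pseudogenes stay open for Pkm2, Eno1, Aldoa and similar genes, although Slc2a1 differed as well (log2 change -1.62), and genotype cannot be told apart from leukaemia or batch.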
